A study of Rattus norvegicus with 10 samples.

How the data were processed

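Small RNA sequencing was done on RNA from the hippocampus of Wistar rats aged 10 weeks, per the labels. They place 5 libraries in a sham-operated group and 5 in a 2-VO group, in which both common carotid arteries were occluded to lower the blood supply of the brain. The time between operation and sampling is not given in the sources used here. Total RNA was isolated with Trizol, ligated to adapters, amplified and selected by size on a gel with a NEBNext small RNA kit, per the labels' protocols. Those protocols name no molecular identifiers, so PCR copies are taken to be counted as reads. Nothing in the labels says that the libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical. Replicate numbers are those of the sample titles (sham 1 to 5, and 2-VO 3, 5, 6, 7 and 8).

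The deposited table holds 765 rat miRNAs by mature name with an RPM value, a read count relative to the reads of the library, for each library, per the file headers. The submitters' processing notes name bcl2fastq, BWA and the rat build rn6. The annotation, the treatment of reads with several matches and the reads that form the divisor are not given in the sources used here. No genome of that build was used here, so no coordinates are given.

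The deposited RPM values show part of what the authors did. All 4962 values above 0 were whole numbers of reads, within 0.01 reads, at a single divisor per library of 13032805 to 13850400 reads. The smallest value above 0 stood for 10 reads in each library. Smaller counts are therefore taken to be listed as 0. A value of 0 then stands for fewer than 10 reads, which is a limit of 0.722 to 0.767 RPM depending on the library. The listed miRNAs summed to 60.3% to 78.0% of the divisor, so it holds reads outside the table, and each RPM value depends on their share. In 9 pairs of rows the values lay within 0.05 of each other on the log2 scale in each library, such as miR-210-3p and miR-3574, and these reads are counted under both names. Each pair of libraries of a group differed by far more than counting error (chi-square of at least 96.6 per degree of freedom), so none was taken for a second sequencing of another. Libraries made more than once from the same RNA can differ by more than counting error too and are not excluded.

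From these values log2(RPM + 1) was computed for the 474 miRNAs with a mean of at least 1 RPM over the 10 libraries, and 237 of the 765 were listed at 0 throughout. The groups were compared with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend, two-sided, no covariate), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(RPM + 1) scale, which understates the change of low miRNAs. A total of 21 miRNA lists (cell types, neighbouring tissue, processes, seed families and clusters) were tested with limma's camera at a preset correlation of 0.01 between members, beside camera with an estimated correlation and limma's fry. Camera compares a list with the other miRNAs, while fry tests it against no change. The ratio of the 5p to the 3p arm was tested with limma for 132 hairpins with both arms kept. For 24 measures of library composition an exact two-sided permutation test over all 252 assignments was used, whose smallest possible p is 0.0079. Intervals are 95% and cover the spread between libraries.

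The comparison, the lists, the other settings and the rule for named miRNAs were written before the data were examined, apart from 3 settings (scaling to the listed miRNA reads, 1 row of each near-identical pair, and voom). The tests of technical explanations were written after first results were seen, most of them before their own values were known. The readings of some were later changed to undecided, with their values unchanged. For the share of miRNAs lower in 2-VO, the tests of the divisor and of 2-VO replicate 3 were first read as fitting the explanation. The test with a pseudocount of 5 was first read as against low values as the explanation of the list that passed. Over other splits, the counts of miRNAs and of hairpins past the threshold were first read as fitting chance. The tests on why 2-VO replicate 3 stood apart were dropped without being run. With fewer than 20 miRNAs passing, the rule named all that passed and then those with the smallest p up to 20, stated as not passing. It added the 10 most abundant, the members of each list with the smallest p among those of at least 10 RPM, hairpins that pass, and 12 miRNAs of ischaemia, inflammation, neurons, vessels and blood. The rule allowed 2 to 4 members per list, and the number 2 was set after the data were seen. The planned count models on whole reads were not run, because no value under 10 reads is listed, and limma's voom on the whole reads was added in their place. Other settings changed the pseudocount, the filter, the scaling, library weights, the robust option, the test per miRNA and the block, or left out each library in turn. The numbers 3 and 5 occur in both groups, but nothing says that they pair animals, so the main comparison has no block.

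The functions were tested on simulated data with the means and spread of the 474 miRNAs, in 20 simulations of 2-VO against sham. With 20 miRNAs changed at each size, the test recovered 16.2% of those changed 1.25-fold, 66.5% of those changed 1.5-fold and 94.8% of those changed 2-fold, and 4.82% of its calls were false. Without any change it made 0.05 calls per simulation. All sizes were changed in the same simulations, which eases the adjusted threshold. The spread was drawn independently for each miRNA, so these rates do not cover miRNAs that vary together between libraries.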

Results

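Mature miRNAs were measured by small RNA sequencing in the hippocampus of 10-week-old Wistar rats, in 5 sham-operated libraries and 5 libraries of the 2-VO group, in which both common carotid arteries were occluded. The operation is a model of chronic cerebral hypoperfusion. The reads behind the RPM values totalled 13032805 to 13850400 per sham library and 13095384 to 13839174 per 2-VO library. Of these, 71.9% ± 4.47 and 69.3% ± 7.24 fell on the listed miRNAs (SD, n = 5 each), with the lowest share, 60.3%, in 2-VO replicate 3. These shares count the reads of near-identical rows under both names, and the repeated rows held 2.46% of the listed RPM. Between 482 and 508 miRNAs had a value above 0 in a library.

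The most abundant miRNA over the 10 libraries was miR-9a-5p, a miRNA of neural progenitors and neurons. It took 18.7% of the listed RPM, with 133063 ± 14839 RPM in sham and 131766 ± 13332 RPM in 2-VO libraries (SD, n = 5). miR-128-3p, a neuron-enriched miRNA, followed with 54749.6 ± 3993 and 50299 ± 6612 RPM. Next came miR-127-3p of the imprinted Dlk1-Dio3 cluster, miR-99a-5p, let-7g-5p, let-7f-5p, miR-26a-5p, let-7i-5p, miR-7a-5p and miR-218a-5p. These 10 miRNAs held 57.4% ± 0.877 of the listed RPM in sham and 57.9% ± 0.717 in 2-VO libraries (SD, n = 5, exact two-sided permutation test, p = 0.39). Their log2 fold changes ran from -0.13 for miR-128-3p to 0.0098 for let-7g-5p, and those of miR-9a-5p, miR-26a-5p, miR-99a-5p, let-7i-5p and miR-218a-5p changed sign under at least 1 other scaling. Of the 24 measures of composition 0 passed (exact permutation tests, smallest unadjusted p = 0.12, all adjusted p = 0.98). The neuron-enriched list took 30.0% ± 0.781 of the listed RPM in sham and 30.4% ± 0.381 in 2-VO libraries.

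The comparison of 2-VO with sham asks which hippocampal miRNAs differ after carotid occlusion. Of 474 miRNAs, 0 passed (limma's moderated test with Benjamini-Hochberg adjustment, smallest adjusted p = 0.44), and 0 passed with voom (25 at an unadjusted p under 0.05). An exact permutation test per miRNA gave 32 at that level, and its smallest possible p of 0.0079 is too large for a few miRNAs to pass among 474. The lowest p values belonged to miRNAs with lower levels in 2-VO, led by miR-27a-5p and miR-204-5p, while miR-34a-5p and miR-210-3p had higher levels. An unadjusted p under 0.05 was found for 24 miRNAs, of which 4 were higher and 20 lower in 2-VO. The split was 14 higher and 21 lower scaled to the listed miRNA reads, and 19 and 19 with TMM factors. With 1 row of each near-identical pair it was 3 higher and 20 lower, since miR-3574 repeats miR-210-3p. The number over all rows was 12 without sham replicate 2, 14 without sham replicate 3, 37 without sham replicate 5 and 42 without 2-VO replicate 6 or 8. For 44 of the 67 miRNAs named here, leaving out 1 library turned the sign of the log2 fold change (17) or moved it by over 1.5 times (27). The 95% interval of the fold change lay within 1.5-fold in either direction for 406 of the 474 miRNAs and within 2-fold for 461.

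miR-204-5p, which is abundant in choroid plexus and pigment epithelium, stood at 646 ± 144.7 RPM in sham and 432 ± 75.7 RPM in 2-VO libraries (SD, n = 5), a log2 fold change of -0.57 ± 0.15 (SE; limma adjusted p = 0.44). Its paralog miR-211-5p stood at 4.18 ± 0.757 and 2.55 ± 0.846 RPM. miR-27a-5p had the smallest p of all, with 11.9 ± 1.72 RPM in sham and 8.11 ± 0.880 RPM in 2-VO libraries (log2 fold change -0.49 ± 0.13, limma adjusted p = 0.44). The groups did not overlap for miR-27a-5p, miR-666-5p and miR-877, which are 3 of the 474 miRNAs, where chance gives 0.794%. Lower values in 2-VO that did not pass were also found for miR-676 (415 ± 50.3 against 318 ± 50.5 RPM), miR-298-5p (9.30 ± 2.18 against 6.4 ± 0.741 RPM) and miR-9b-5p (1587 ± 212 against 1272 ± 248 RPM). Further miRNAs below the sham level were miR-1224 (log2 fold change -0.31), miR-149-5p (-0.30), miR-935 (-0.29), miR-125b-1-3p (-0.22) and miR-7a-2-3p (-0.49, or -0.25 without 2-VO replicate 3). From the Dlk1-Dio3 cluster, miR-433-3p stood at 722 ± 73.8 and 603 ± 50.5 RPM, and miR-409b and miR-485-5p had log2 fold changes of -0.31 and -0.29. None of these passed the adjusted threshold.

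Higher values in 2-VO were fewer at this level. miR-34a-5p, a transcriptional target of p53, stood at 40.9 ± 6.27 RPM in sham and 55 ± 8.02 RPM in 2-VO libraries (log2 fold change 0.42 ± 0.14, limma adjusted p = 0.64). miR-210-3p, which hypoxia-inducible factor induces, stood at 62.5 ± 8.53 and 75.9 ± 7.86 RPM (log2 fold change 0.28 ± 0.12, limma adjusted p = 0.76). The row miR-3574 held the same values as miR-210-3p, so these reads cannot be assigned to either name. miR-6215 stood at 21.7 ± 4.85 and 44.2 ± 26.9 RPM, with its highest value, 86.5 RPM, in 2-VO replicate 3.

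**Figure D1:**
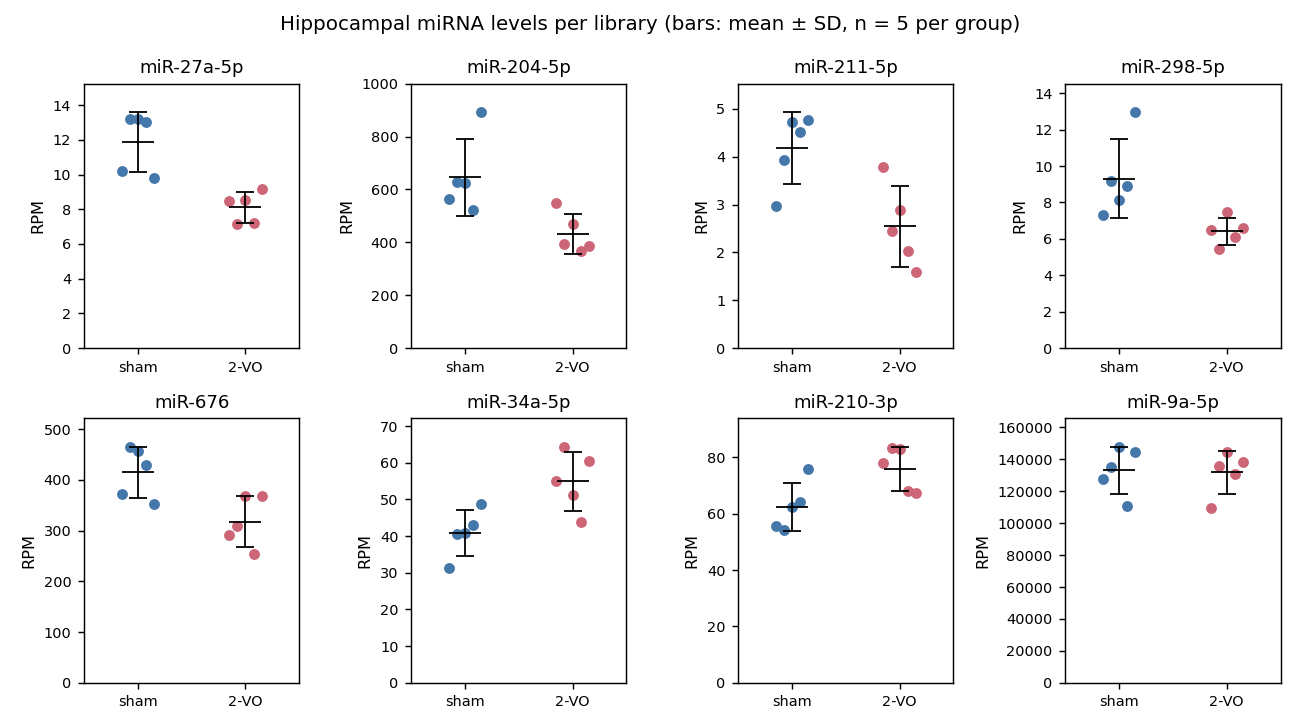
RPM per library (vertical axis, linear from 0) of the 6 miRNAs with the smallest p, of miR-210-3p and of the most abundant miRNA, miR-9a-5p, in sham and 2-VO hippocampus; each point is a library, and bars give mean ± SD (n = 5 per group). The groups of miR-27a-5p do not overlap, those of miR-9a-5p do, and 0 of the miRNAs shown passed the adjusted threshold.

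**Figure D2:**
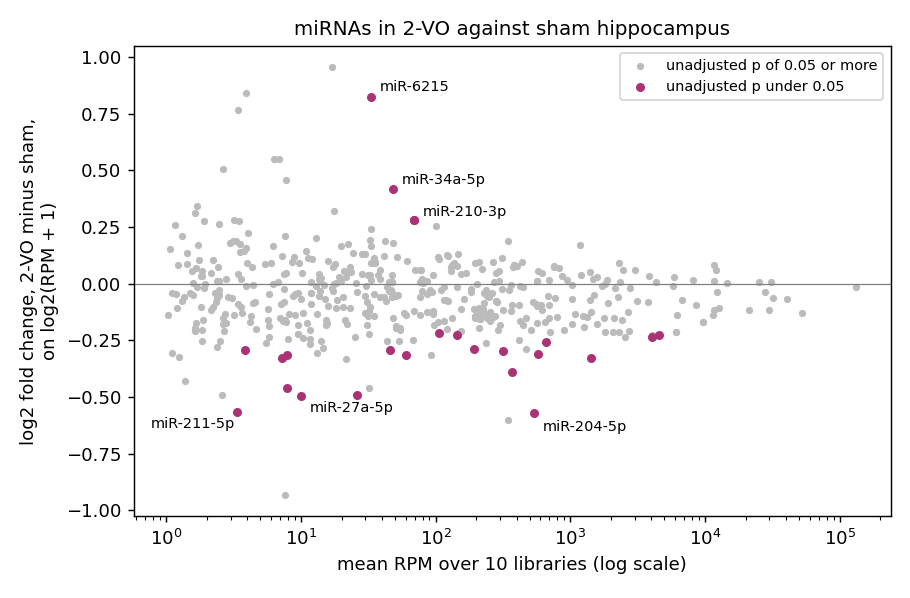
Log2 fold change of 2-VO against sham on the log2(RPM + 1) scale (vertical axis) against mean RPM over 10 libraries (horizontal log axis) for 474 miRNAs. The 24 purple points have an unadjusted p under 0.05, of which 20 lie below 0 and 4 above, a split of 21 and 14 scaled to the listed miRNA reads, and 0 pass after adjustment.

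The miRNAs fixed in advance for ischaemia, inflammation, neurons, vessels and blood did not pass either. Of them, only miR-210-3p had a 95% interval of the log2 fold change that left out 0 (0.029 to 0.53, not adjusted for the number of miRNAs). miR-21-5p, which inflammation induces, stood at 3798 ± 509 RPM in sham and 3894 ± 545 RPM in 2-VO libraries (SD, n = 5), and the 95% interval of its log2 fold change ran from -0.22 to 0.29. The intervals of miR-146a-5p (-0.17 to 0.35), a brake on inflammatory signalling, of the activity-regulated miR-132-3p (-0.15 to 0.25) and of the endothelial miR-126a-3p (-0.29 to 0.15) also held 0. So did those of miR-195-5p (-0.10 to 0.35), miR-181c-5p (-0.29 to 0.29), miR-153-3p (-0.22 to 0.49) and the neuronal miR-124-3p (-0.41 to 0.29). miR-155-5p, a miRNA of activated immune cells, stood at 1.80 ± 0.328 and 1.87 ± 0.369 RPM. miR-451-5p, a red blood cell miRNA, ran from 5.76 RPM in 2-VO replicate 3 to 36.2 RPM in 2-VO replicate 8.

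Of the 21 lists, only that of miRNAs of other brain regions and epithelium passed, with 7 of its 9 kept members higher and 2 lower in 2-VO and a median 0.56 above that of the other miRNAs on the log2 scale (limma's camera, preset correlation, adjusted p = 0.0028). The call was lost with members' own correlation (adjusted p = 0.80 with an estimated correlation), and 0 members passed over all miRNAs or adjusted over the list alone. At the preset correlation at least 1 list passed in 92 of 100 splits of the libraries into 5 and 5, the real one included. miR-10a-5p, a Hox-cluster miRNA of hindbrain and spinal cord, stood at 12.7 ± 9.72 RPM in sham and 21.4 ± 8.79 RPM in 2-VO libraries (SD, n = 5). The endocrine miR-375-3p stood at 39.6 ± 24.8 and 24 ± 4.87 RPM. Of members chosen after their values were seen, miR-200a-3p reached 21.9 RPM and miR-200b-3p 18.4 RPM in 2-VO replicate 3, against at most 4.70 and 3.97 RPM in the other libraries. The sensory-cell miRNAs miR-182 and miR-183-5p were also highest there, at 15.9 and 18.9 RPM. Without 2-VO replicate 3 the list's median lay 0.21 above that of the other miRNAs (camera adjusted p = 0.18), without sham replicate 3 the adjusted p was 0.084, and among the 3 members of at least 10 RPM the relative median was -0.061. The call was also lost under other scalings, though the relative median stayed at 0.54 to 0.56, with camera adjusted p of 0.067 scaled to the listed miRNA reads, 0.074 with TMM factors, 0.062 with median-of-ratios factors and 0.14 after quantile normalization, and at 0.065 with array weights (relative median 0.45).

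The other 20 lists did not pass. Their counts of higher and lower members depend on the scaling, since 62.2% of all 474 miRNAs were lower as deposited, 49.4% scaled to the listed miRNA reads and 47.7% with TMM factors. Of their members, 3 had an adjusted p under 0.05 adjusted over the list alone (limma) and 0 over all miRNAs. These were miR-204-5p and miR-211-5p of the choroid plexus and ependyma list, and miR-27a-5p of the miR-23/27/24 clusters. In the choroid plexus and ependyma list 8 of 9 members were lower in 2-VO (median log2 fold change -0.13, camera adjusted p = 0.19), among them miR-448-3p at 25.0 ± 15.8 against 17.8 ± 6 RPM. Its median was 0.0064 without sham replicate 5, which held 0.280% of the listed RPM in this list against 0.130% to 0.187% in the other sham libraries, and the list passed without sham replicate 1 (camera adjusted p = 0.012), though over all libraries its adjusted p was 0.88 with an estimated correlation. In the miR-23/27/24 clusters 7 of 10 were lower (median -0.11, camera adjusted p = 0.43), with miR-27b-5p at 14.5 ± 1.15 against 11.7 ± 2.70 RPM, while miR-23b-3p stood at 1116 ± 84.6 against 1255 ± 83.8 RPM. The number of lists that passed was 5 without sham replicate 1 or 2-VO replicate 6, 6 without sham replicate 4, 0 without sham replicate 3, and 2 without sham replicate 5, 2-VO replicate 7 or 2-VO replicate 8. At the preset correlation the let-7 family, the miR-17-92 and paralog clusters and the miR-99, miR-100 and miR-125 clusters passed in 3 of 22 other settings each, the choroid plexus and ependyma list and the miR-15, miR-16 and miR-195 family in 2, and the hypoxia-responsive and the endothelial and vascular wall lists in 1. With an estimated correlation 0 of the lists passed (camera, smallest adjusted p = 0.80).

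Among the cell-type lists, 12 of 16 neuron-enriched members were lower (median -0.066), with miR-129-1-3p at -0.22 and miR-128-3p at -0.13 on the log2 scale. Of the oligodendrocyte and myelin miRNAs 4 of 7 were lower, with miR-338-5p at -0.16 and miR-32-5p at 0.14. In the astrocyte-enriched list 5 of 8 were lower, with miR-24-3p at -0.21 and miR-23b-3p at 0.17, and a median of -0.0100 that turned positive with TMM factors, median-of-ratios factors, quantile normalization and scaling to listed reads. The leukocyte and microglia list had 4 of 7 members higher (miR-142-3p 0.18, or 0.046 without 2-VO replicate 5, and miR-342-3p -0.16, or -0.077 without 2-VO replicate 3). The red blood cell list had 3 of 4 higher (miR-451-5p 0.17, miR-486 -0.072), and it passed without 2-VO replicate 3 (camera adjusted p = 0.0085), though over all libraries its adjusted p was 0.88 with an estimated correlation. In the endothelial and vascular wall list 5 of 9 were higher, with a median of 0.0086, or -0.0076 with RPM recomputed without the 5 most abundant miRNAs (miR-10a-5p 0.96, miR-126a-3p -0.070), and it shares miR-10a-5p and miR-10b-5p with the list of other brain regions and epithelium. The camera adjusted p of these 6 lists lay between 0.10 and 0.86.

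Among the lists of processes, 6 of 10 hypoxia-responsive miRNAs were higher (median 0.0084, or -0.0082 with RPM recomputed without the 5 most abundant miRNAs, camera adjusted p = 0.070), with miR-210-3p at 0.28 and miR-199a-5p at 0.19. Of the miRNAs studied in cerebral ischaemia or hypoperfusion 13 of 20 were higher (median 0.035, camera adjusted p = 0.069), with miR-210-3p again a member and miR-497-5p at 0.19. This list passed in 6 of 22 other settings (smallest camera adjusted p = 0.015, without 2-VO replicate 7) and with camera on ranks, but not with an estimated correlation (adjusted p = 0.88). In the inflammation-responsive list 5 of 9 were higher, with miR-34a-5p at 0.42 and miR-146b-5p at -0.21 (camera adjusted p = 0.44). In the activity-regulated list 5 of 9 were lower, with miR-485-5p at -0.29 and miR-212-3p at 0.25, and the median of -0.016 turned positive with TMM factors, median-of-ratios factors, quantile normalization and scaling to listed reads (camera adjusted p = 0.72).

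Among families and clusters, 51 of 76 Dlk1-Dio3 members were lower (median -0.062, camera adjusted p = 0.43). The let-7 family had 7 of 9 lower (miR-98-5p -0.29, let-7a-5p -0.21, camera adjusted p = 0.19), and the miR-99, miR-100 and miR-125 clusters 9 of 10 (miR-125a-5p -0.23, miR-125b-1-3p -0.22, camera adjusted p = 0.070). The miR-15, miR-16 and miR-195 family had 5 of 7 higher (miR-497-5p 0.19, miR-195-5p 0.12, camera adjusted p = 0.070), and the miR-17-92 and paralog clusters 8 of 11 (miR-19b-3p 0.32, miR-17-5p 0.18, camera adjusted p = 0.070). The miR-29 family had 4 of 6 higher (miR-29c-3p 0.059, miR-29c-5p -0.056) and the miR-30 family 8 of 11 lower (miR-30b-3p -0.16, miR-30d-5p -0.11). The miR-181 family had 4 of 7 lower (miR-181a-1-3p 0.084, miR-181a-5p -0.080), with a median of -0.0049 that turned positive with TMM factors, median-of-ratios factors, quantile normalization and scaling to listed reads. The camera adjusted p of these last 3 families lay between 0.43 and 0.91. Camera, which compares a list with the other miRNAs, gave an upward direction to the astrocyte-enriched, oligodendrocyte and myelin, activity-regulated and miR-181 lists, whose median and mean fold changes lay below 0.

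**Figure D3:**
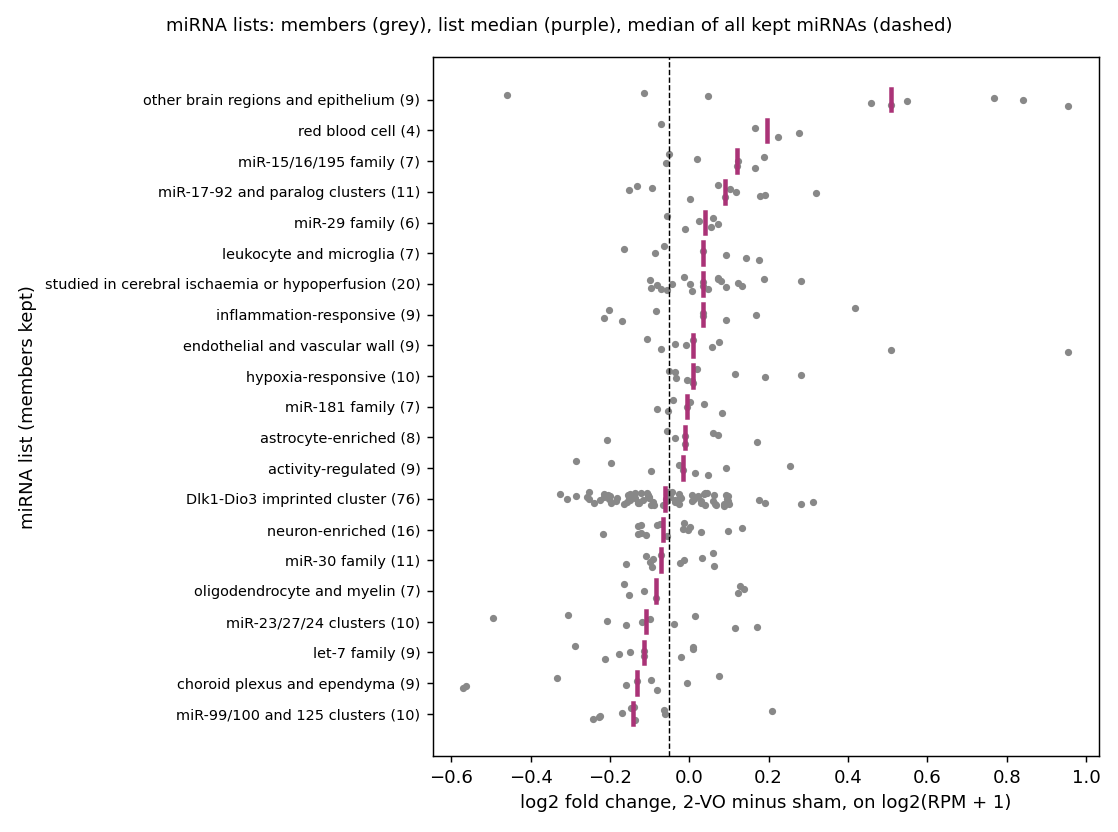
Log2 fold change of 2-VO against sham (horizontal axis) for the kept members of each of 21 miRNA lists (rows, members kept in parentheses); grey points are miRNAs, purple bars list medians, and the dashed line the median of all 474 miRNAs, -0.051. The list of other brain regions and epithelium has the highest median, 0.51, and that of the miR-99, miR-100 and miR-125 clusters the lowest, -0.14.

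The ratio of the 5p to the 3p arm was compared for 132 hairpins, to ask whether the arms of a precursor differed unequally between the groups. Of these, 0 passed (limma, smallest adjusted p = 0.12), and 15 had an unadjusted p under 0.05, with 7 ratios higher and 8 lower in 2-VO. The smallest p values belonged to miR-204 and miR-27a, named after their values were seen. The log2 ratio of miR-204 was 6.81 ± 0.158 in sham and 6.32 ± 0.243 in 2-VO libraries (SD, n = 5), a difference of -0.49 ± 0.13 (SE; limma adjusted p = 0.12), with miR-204-3p at 4.75 ± 1.16 and 4.35 ± 0.263 RPM. For miR-27a the log2 ratio was -5.51 ± 0.119 in sham and -5.91 ± 0.185 in 2-VO libraries, a difference of -0.40 ± 0.10 (limma adjusted p = 0.12), with miR-27a-3p at 585 ± 56.7 and 549 ± 81.7 RPM. Without 2-VO replicate 3 the miR-204 ratio passed (difference -0.59, limma adjusted p = 0.018), and without sham replicate 5 the ratios of miR-23b, miR-329 and miR-409a did (limma adjusted p = 0.049 each).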

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

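The values below lay far from the other libraries of their group, with a gap to the nearest library above 0.71 of the range of 5 libraries. Of 182 groups of 5 values, 11 did so, where chance alone gives about 9.1, and no explanation was tested for any of them. In the sham group, miR-7a-2-3p was highest in replicate 2 (36.1 RPM, others 27.7 to 29.4) and miR-19b-3p in replicate 5 (24.2 RPM, others 12.4 to 14.9). Sham replicate 1 had the lowest miR-98-5p (406 RPM, others 530.3 to 551) and the lowest miR-181a-5p (2833 RPM, others 3950.4 to 4467). In the 2-VO group, replicate 3 had the lowest miR-7a-2-3p (10.4 RPM, others 22.7 to 29.1) and the highest share of the miR-181 family (1.06% of the listed RPM, others 0.682% to 0.753%). Replicate 6 of the 2-VO group had the highest miR-125a-5p (4993 RPM, others 3810 to 4078) and the highest let-7i-5p (29810 RPM, others 23390 to 24774). miR-212-3p was highest in 2-VO replicate 8 (153.8 RPM, others 91.0 to 104), miR-129-1-3p was highest in 2-VO replicate 5 (157 RPM, others 126.1 to 133), and miR-195-5p was lowest in 2-VO replicate 7 (108 RPM, others 131 to 141).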

How the results depend on the processing

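The alternatives scaled to the listed miRNA reads, with 1 row of each near-identical pair and with voom were chosen after seeing the data, and the planned count models on whole reads were not run. The count of miRNAs past the threshold was 0 under each alternative except the replicate block (the exact permutation test per miRNA could hardly pass any), and the count of composition measures was 0 throughout. The arm count was 0 except that it ran from 0 to 3 when each library was left out in turn. The number of lists that passed was 2 without a filter and among miRNAs of at least 10 RPM, 3 with camera on ranks, and 0 with TMM factors, median-of-ratios factors, quantile normalization, array weights, scaled to the listed miRNA reads, camera with an estimated correlation and fry. It ran from 0 to 6 when each library was left out. The relative median of the list of other brain regions and epithelium was 0.56 in the comparison reported and with camera's estimated correlation, which ended its call. Fry, which does not test this relative median, did not pass the list either. The relative median was 0.55 with TMM factors, 0.56 with median-of-ratios factors, 0.54 after quantile normalization, 0.45 with array weights and 0.55 scaled to the listed miRNA reads, none of which passed. It ran from 0.21, without 2-VO replicate 3, to 0.73, without sham replicate 5, when each library was left out. The number at an unadjusted p under 0.05 was 38 with TMM factors, 37 with median-of-ratios factors, 39 after quantile normalization and 43 with array weights, and ran from 12 to 42 when each library was left out. Among miRNAs of at least 10 RPM the relative list medians of opposite sign were oligodendrocyte and myelin 0.059 and other brain regions and epithelium -0.061. With TMM factors the log2 fold changes of opposite sign were miR-99a-5p 0.0012, miR-29c-5p 0.0065, miR-26a-5p 0.030, miR-124-3p 0.0079 and miR-9a-5p 0.052. With median-of-ratios factors the log2 fold changes of opposite sign were miR-26a-5p 0.020 and miR-9a-5p 0.042. After quantile normalization the log2 fold changes of opposite sign were miR-181a-5p 0.0038, miR-124-3p 0.025 and miR-181c-5p -0.032, and the relative list median of opposite sign was neuron-enriched 0.0014. With array weights the log2 fold changes of opposite sign were miR-29c-5p 0.013, miR-7a-5p 0.019, miR-486 0.020 and miR-9a-5p 0.025, and the relative list medians of opposite sign were neuron-enriched 0.023 and miR-181 family -0.0083. With the replicate block the log2 fold changes of opposite sign were miR-199a-5p -0.15, miR-451-5p -0.37, miR-21-5p -0.011, miR-155-5p -0.12, let-7i-5p -0.15, let-7g-5p -0.28 and miR-218a-5p -0.24, and the relative list medians of opposite sign were neuron-enriched 0.067, oligodendrocyte and myelin 0.13, red blood cell -0.18, miR-23/27/24 clusters 0.16 and Dlk1-Dio3 imprinted cluster 0.0036. With RPM recomputed without the 5 most abundant miRNAs the log2 fold changes of opposite sign were let-7i-5p -0.0081, miR-181c-5p -0.014 and miR-218a-5p -0.015. Scaled to the listed miRNA reads the log2 fold changes of opposite sign were miR-29c-5p 1.4e-04, miR-26a-5p 0.023, miR-124-3p 0.0012 and miR-9a-5p 0.045. The miR-29c-5p log2 fold change thus took both signs across the scalings. When each library was left out, log2 fold changes that took both signs were miR-21-5p -0.032 to 0.10, let-7i-5p -0.051 to 0.036, let-7g-5p -0.053 to 0.060, miR-124-3p -0.17 to 0.033, miR-9a-5p -0.077 to 0.052, miR-155-5p -0.024 to 0.098, miR-218a-5p -0.071 to 0.086, miR-132-3p -0.0028 to 0.082, miR-181c-5p -0.096 to 0.076, miR-127-3p -0.13 to 0.0015, miR-29c-5p -0.10 to 0.024, miR-7a-5p -0.22 to 0.13, miR-486 -0.21 to 0.072, miR-29c-3p -0.11 to 0.16, miR-181a-5p -0.19 to 0.0010, miR-26a-5p -0.077 to 0.014 and miR-451-5p -0.053 to 0.56, and relative list medians that took both signs were miR-30 family -0.065 to 0.029, miR-181 family -0.026 to 0.075, neuron-enriched -0.033 to 0.026, oligodendrocyte and myelin -0.085 to 0.051, choroid plexus and ependyma -0.27 to 0.041, activity-regulated -0.0042 to 0.073, Dlk1-Dio3 imprinted cluster -0.049 to 0.011 and astrocyte-enriched -0.034 to 0.068. Lists that passed then but not in the comparison reported, at the preset correlation, were the endothelial and vascular wall, choroid plexus and ependyma, ischaemia and let-7 lists without sham replicate 1, the hypoxia-responsive, ischaemia, miR-15, miR-16 and miR-195 family, miR-17-92 and miR-99, miR-100 and miR-125 clusters without sham replicate 4, the miR-17-92 clusters without sham replicate 5 or 2-VO replicate 8, the red blood cell list without 2-VO replicate 3, the ischaemia, let-7, miR-15, miR-16 and miR-195 family and miR-99, miR-100 and miR-125 clusters without 2-VO replicate 6, and the ischaemia list without 2-VO replicate 7. Without sham replicate 3 or 2-VO replicate 3 the list of other brain regions and epithelium lost its call. Other lists that passed were the ischaemia list without a filter, the ischaemia list and the miR-99, miR-100 and miR-125 clusters among miRNAs of at least 10 RPM and with camera on ranks, and the choroid plexus and ependyma list and the let-7 family with the replicate block. Apart from the estimated correlation, which widens the list test by construction, the cause was not tested. The deviations of same-numbered libraries correlated at -0.058 (number 3) and -0.18 (number 5). So few correlations cannot show whether these numbers pair the libraries. With the title number as a replicate block, 8 miRNAs, 3 lists and 0 hairpins passed, but this fit rests on the 4 libraries that share numbers, with 1 residual degree of freedom per miRNA and the spread pooled over miRNAs. The smallest listed value of 10 reads limits statements on low miRNAs.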

Other observations

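Some miRNAs varied widely between libraries of a group. Over the 339 miRNAs of at least 10 RPM the median SD within groups was 0.20 on the log2 scale. It was 0.97 for miR-10a-5p, 0.77 for the endocrine miR-375-3p, 0.71 for the red blood cell miR-451-5p and 0.68 for miR-448-3p. miR-1298 ran from 207 RPM in 2-VO replicate 6 to 993 RPM in sham replicate 5, and miR-34c-5p, a miRNA of ciliated cells, from 290.2 RPM in sham replicate 1 to 1061 RPM in sham replicate 5. The abundant miR-7a-5p ran from 9928 RPM in 2-VO replicate 3 to 27352 RPM in sham replicate 5. Among miRNAs known best from other organs, the liver miRNA miR-122-5p stood at 2.67 ± 0.554 RPM in sham and 2.06 ± 0.697 RPM in 2-VO libraries (SD, n = 5), the muscle miRNA miR-1-3p at 12.1 ± 2.60 and 11.8 ± 3.29 RPM, and the heart miRNAs miR-208a-3p and miR-208b-3p were listed at 0 in all 10 libraries. Others of this kind were higher, such as the heart and muscle miRNA miR-499-5p at 168 ± 44.0 and 158 ± 30.3 RPM. On the first principal component of the 10 libraries, which held 27.4% of the variance, 2-VO replicate 3 lay at 8.13 and the others between -3.71 and 1.97.

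Of the tests weighed here, those of the divisor for miR-204-5p, of misassigned miR-211-5p reads, of 2-VO replicate 3 for the list of other brain regions and epithelium, and of other splits for the count of miRNAs changed were chosen only after the result was seen, and the test with a pseudocount of 5 was written once that list had passed. The lower values of miR-204-5p and miR-211-5p in 2-VO did not pass over all miRNAs. They were singled out by their small p among 474 miRNAs, so chance is not excluded, and it was not tested for them. The operation itself also stays among the open explanations. The lower value of miR-204-5p did not rest on the divisor of the RPM values or on 1 library alone. Its log2 fold change was -0.51 ± 0.16 (SE) scaled to the listed miRNA reads. It was at most -0.45 ± 0.13 when each library was left out. Less choroid plexus and ependyma in the 2-VO dissections stays open. The 6 other members of that list, without any arm of either hairpin, had a median of -0.11. The standard error of the mean over members was 0.057, which treats members as independent and leaves out the spread between libraries. The median did not fall as low as the value set for this explanation. Nor did it clear the value set against this explanation by more than that error. The median of all 474 miRNAs was -0.051. The median of the whole list was 0.0064 without sham replicate 5. Less tissue alone would lower both arms of miR-204, while its 5p to 3p ratio was lower in 2-VO (log2 difference -0.49 ± 0.13, SE, limma adjusted p = 0.12). That ratio did not pass and rests on a 3p arm of low RPM, so it does not decide the question. Whether part of the miR-211-5p signal is misassigned miR-204-5p reads stays open. The ratio of their reads did not differ beyond counting error over the 10 libraries (chi-square of 16.2 on 9 degrees of freedom, p = 0.063). A p that misses a threshold does not show equal ratios, and paralogs that vary together would give a steady ratio too.

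More miRNAs were lower than higher in 2-VO, 62.2% of the 474, and what this rests on stays open. Scaled to the listed miRNA reads, 49.4% were lower, but such scaling takes out any shift that most miRNAs share and so does not test the divisor as its cause, and the listed RPM sum did not pass between the groups (exact permutation test, p = 0.52). Leaving out 2-VO replicate 3 gave 50.2%, but a drop is not particular to it, since leaving out another library gave 53.8% (2-VO replicate 7) to 70.5% (sham replicate 1). Of 100 splits of the 10 libraries into 5 and 5, drawn at random with the real one included, 62 gave as uneven a share (highest other 92.0%), so chance cannot be excluded.

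The higher values of the list of other brain regions and epithelium may rest largely on 2-VO replicate 3, without which its median lay 0.21 above that of the other miRNAs (camera adjusted p = 0.18). Low values near the limit of 10 reads stay open too. With a pseudocount of 5 the call held at the preset correlation (camera adjusted p = 0.0028), but the relative median went from 0.56 to 0.35, and it was -0.061 among the 3 members of at least 10 RPM. Over the list's 25 alternatives the adjusted p of camera or fry ran from 1.6e-11 to 0.95. These alternatives include the replicate block, which rests on few libraries. When each library was left out, the smallest camera adjusted p was 1.5e-04. The highest came from fry, which tests the list against no change, and camera with an estimated correlation gave 0.80. Tissue taken from beside the hippocampus and an effect of the operation were not tested apart.

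Chance cannot be excluded for the number of miRNAs at an unadjusted p under 0.05 or for the lists. In the same 100 splits, 34 gave as many such miRNAs as the real 24 (highest other 103), and as many lists as the real 1 passed in 92 (highest other 7). For miRNAs and for hairpins past the threshold the real count was 0, which each split reaches by construction (100 and 100 of the splits, highest other 3 for each), so these comparisons say nothing about chance. The split with 103 miRNAs set sham replicates 1, 4 and 5 and 2-VO replicates 3 and 7, among them the 4 libraries with the lowest share of listed reads, against the rest. Its count is several times the real one and may reflect a structure of the samples other than their groups, but it is the largest of 99 draws. Further draws came close, with 101, 100 and 90 such miRNAs. In those draws 91.6%, 92.0% and 90.9% of all miRNAs moved the same way, against 89.2% in the split with 103. The splits share libraries, and no such structure was tested.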
